A study of Homo sapiens with 6 samples.

How the data were processed

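Polyadenylated RNA was sequenced in bulk from OE33 cells, an established line derived from a human adenocarcinoma of the esophagus. The 6 libraries fell into 2 groups of 3 biological replicates, untreated control cells and cells given acidified bile salts (ABS). ABS cells were held for 20 min in medium at pH 4.0 that lacked supplements and held 200 µM bile salts, and were washed and returned to full growth medium for 6 h before harvest. The composition of the bile salt mixture was not stated. No group was labelled as given acid alone, bile salts alone or the exposure medium alone, and whether control cells had a change into medium without supplements was not stated. The ABS contrast therefore covers acid and bile salts together, and also that medium and the handling unless control cells had them too. The labels gave no sequencing or culture batch and paired no control library with an ABS library.

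The deposited table holds raw counts per gene, whole numbers in 1 column per library, together with gene identifiers, names, biotypes and lengths. Per the labels, the submitters used HISAT2 2.0.5 and featureCounts 1.5.0-p3 with the GRCh38 genome. The annotation release, the strand setting and the treatment of reads that map to several places were not stated there. All 58735 gene identifiers were found in GENCODE release 29 (Ensembl 94) with identical coordinates, and positions are given on GRCh38. Library totals lay between 22145676 and 25235686 counts, and 33778 genes had 0 counts in every library. At this depth a count of 3 in a library, the limit that a count of 0 allows, corresponded to between 0.119 and 0.135 CPM, the count scaled to a common library size. Intervals and such limits cover counting error only, since the reads carried no molecular identifiers.

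Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, counts were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood F-test compared ABS with control with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Group levels are means of TMM-scaled CPM with the standard deviation (SD) over 3 libraries. Principal components used log2 CPM with a prior count of 2. The procedure was also tested on simulated data made from the control and ABS count levels with 3 libraries per group. In that simulation 45.3% of 64 genes changed 1.5-fold were recovered, 79.4% of 63 genes changed 2-fold and 88.3% of 60 genes changed 4-fold, and 12 of 144 calls were false. In a simulation without any change, 1 gene and 0 lists were called, and 4.88% of genes had an unadjusted p under 0.05. Both simulations drew each gene independently and held no separation of the replicate 3 libraries. The 0 lists therefore say nothing of lists whose genes vary together.

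A total of 45 gene lists, 6 of them control lists, was fixed before the data were examined, and so were the tests, their alternatives and the rule for naming genes. The lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the 43 lists with at least 3 tested members. Camera compares a list with the other genes. Its version with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run beside it. Fibroblast markers, with 2 tested members, and endothelial markers, with 1, were too few to test. The lists covered immediate-early genes and MAPK feedback, NF-kB inflammatory genes, JAK-STAT3, interferon response, the unfolded protein response, the integrated stress response, heat shock, NRF2 antioxidant genes, antioxidant peroxidases, metallothioneins, the DNA damage response, base excision repair, double-strand break repair, apoptosis, autophagy, hypoxia, cell cycle phases and sterol, lipid and energy metabolism. They also covered bile acid sensing and transport, acid sensing, lysosomes, ribosomes and their assembly, chromatin modifiers, clock genes, antigen presentation, epithelial differentiation, cell junctions and signalling by EGFR, YAP-TEAD, Wnt, Notch and TGF-beta. Control lists held mitochondrially encoded mRNAs, replication-dependent histones, housekeeping genes and markers of fibroblasts, immune cells and endothelium.

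The rule named the 10 largest changes in each direction among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between groups. It added up to 4 members of each called list, up to 2 of each other list, and a fixed set of genes of interest for reflux whatever their values. All other genes named were chosen after their values were seen, apart from further aryl hydrocarbon receptor targets and *SLC39A10*, which were chosen before their own values were seen. Some genes that the rule named or that passed the threshold are not reported here.

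The alternatives fixed for the gene test were size factors by relative log expression, upper quartile factors, library size alone, no filter beyond a count of 1, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, protein-coding genes alone, a test against a 1.2-fold change, a replicate block and leaving out each library in turn. Those for the lists were the estimated correlation, fry, library size alone, log2 CPM with a trend, the replicate block, leaving out genes held by several lists, and leaving out each library. Leaving out both replicate 3 libraries, a term that set them apart, the latter together with an estimated correlation, and removal of trends with GC content and gene length were added after seeing the data.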

Results

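The series measured gene expression in OE33 cells, a human esophageal adenocarcinoma line, 6 h after a 20 min exposure to ABS and in untreated cells, with 3 libraries per group. Control libraries 1, 2 and 3 held 23683950, 22145676 and 23612697 counts. ABS libraries 1, 2 and 3 held 25235686, 23414287 and 24805821 counts. Between 18127 and 19927 genes were detected per library, and protein-coding genes took 98.3% to 98.5% of the counts. The single comparison, ABS against control, addressed how the transcriptome of these cells differed after an acute exposure that models reflux.

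After ABS, the cytochrome P450 genes *CYP1A1* and *CYP1B1*, which encode enzymes that oxidise foreign compounds and steroids, were 22.6-fold and 8.71-fold higher than in control cells. Metallothionein genes, which encode metal-binding proteins, and *SLC30A1*, which encodes a zinc exporter of the plasma membrane, rose with them, *MT1E* by 9.79-fold and *SLC30A1* by 7.02-fold. Smaller rises were found in genes of the antioxidant response (*GCLM*, *OSGIN1*, *TXNRD1*), of NF-kB and interferon signalling (*RELB*, *IRF1*) and of the AP-1 family (*FOSL1*, *FOSB*). The transcription factor genes *SOX9*, *SOX4* and *SOX13* fell, and so did *ERRFI1*, which encodes a feedback inhibitor of the EGF receptor. Among these genes, *CYP1A1*, *CYP1B1*, *MT1E*, *SLC30A1* and *SOX9* passed the threshold in all 6 fits that left out a library. The others named in this paragraph passed in only 2 to 4 of the 6.

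Of 13768 tested genes, 11837 of them protein-coding, 60 passed the edgeR threshold. Of these, 51 were higher and 9 lower after ABS, and 16 of the higher genes had a log2 fold change of at least 1. The median rise was 1.62-fold, and the 9 lower genes had log2 fold changes between −0.91 and −0.45. The 3 ABS values lay wholly above or below the 3 control values in 1999 of the tested genes, or 14.5%, and in all 60 that passed. Exchangeable libraries would give 10%, but the replicate 3 libraries stood apart, so this share was not tested against chance. The biological coefficient of variation was 11.3%. The count of 60 moved with every library left out. It was 17 without control replicate 1, 12 without control replicate 2, 438 without control replicate 3, 13 without ABS replicate 1, 18 without ABS replicate 2 and 273 without ABS replicate 3. It was 35 with library size alone, 409 without a filter, 233 with DESeq2 and 14 against a 1.2-fold change. In all 6 fits that left out a library, 12 genes passed, namely *CYP1A1*, *CYP1B1*, *TIPARP*, *MT1E*, *MT1F*, *MT1G*, *MT1X*, *SLC30A1*, *SLC16A6*, *DAPP1*, *LINC00511* and *SOX9*.

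The replicate 3 libraries of both groups stood apart from the other 4. The first principal component, with 28.4% of the variance, held the control libraries at −21.6, −20.0 and −8.19 and the ABS libraries at 18.4, 28.9 and 2.60. The second, with 25.9%, held control replicate 3 at −19.0 and ABS replicate 3 at −29.0, with the other libraries between 2.73 and 18.5. A chi-square statistic on raw counts, per degree of freedom, was 4.77 between control replicates 1 and 2, 4.77 between ABS replicates 1 and 2 and 6.74 between control replicate 3 and ABS replicate 3, and lay between 13.6 and 18.9 for all other pairs. Within replicates 1 and 2, 1813 genes passed, and with a term that set the replicate 3 libraries apart 465 passed, each including all 60 genes. Both fits were chosen after seeing the data, and leaving out libraries because they stood apart lowers the spread by construction. All 60 genes had the same sign within replicates 1 and 2 and within the replicate 3 pair, whose difference rests on 1 library per group. This is no separate check, since the groups did not overlap in any of the 60, which fixes these signs. The mitochondrially encoded share of counts was 2.48%, 2.57% and 1.91% in the control libraries and 2.07%, 2.26% and 2.09% in the ABS libraries.

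**Figure D1:**
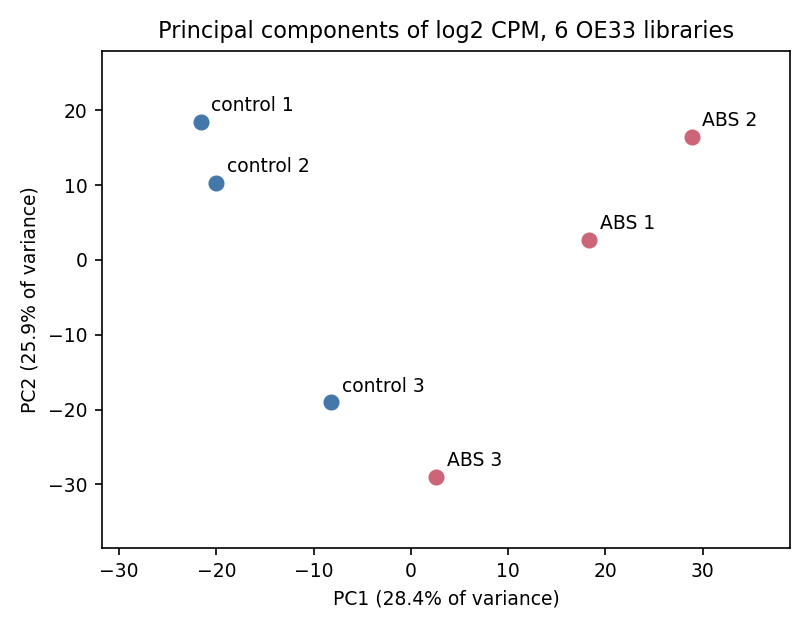
Principal components of log2 CPM for the 6 libraries, with the first component (28.4% of the variance) on the horizontal axis, the second (25.9%) on the vertical axis and 1 point per library, blue for control and red for ABS. The control libraries lie at −21.6 to −8.19 and the ABS libraries at 2.60 to 28.9 on the first component, and the replicate 3 libraries lie at −19.0 and −29.0 on the second.

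*CYP1A1* (ENSG00000140465, chromosome 15, 74719542 to 74725610) rose from 2.44 ± 0.536 CPM in control cells to 55.5 ± 14.4 CPM after ABS (mean ± SD, n = 3 per group). Its log2 fold change was 4.50 ± 0.21 (SE), with an edgeR adjusted p of 4.05e-07. *CYP1B1* (ENSG00000138061, chromosome 2, 38066973 to 38109902) rose from 6.84 ± 1.69 to 59.8 ± 1.75 CPM, a log2 fold change of 3.12 ± 0.15 with the same adjusted p. *TIPARP* (ENSG00000163659, chromosome 3, 156673235 to 156706770), which encodes a mono-ADP-ribosyltransferase, rose from 102 ± 10.1 to 197 ± 20.4 CPM, a log2 fold change of 0.95 ± 0.10 with an adjusted p of 0.000782, and was named after its value was seen. Within replicates 1 and 2 the log2 fold changes were 4.46 for *CYP1A1*, 3.32 for *CYP1B1* and 1.06 for *TIPARP*, and within the replicate 3 pair they were 4.52, 2.78 and 0.72. The 3 genes passed in all 20 alternatives of the gene test, that against a 1.2-fold change included.

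Of 8 tested members of the metallothionein list, 7 metallothionein genes and *SLC30A1*, 7 rose and 0 fell, by the edgeR test over all genes and also when adjusted over the list alone. Their median log2 fold change was 2.77, and the camera adjusted p was 6.58e-24 (adjusted p = 0.113 with an estimated correlation). Without *SLC30A1* the median was 2.74. *MT1E* (ENSG00000169715, chromosome 16, 56625475 to 56627112) rose from 5.63 ± 2.71 to 55.3 ± 5.45 CPM and *MT2A* from 63.7 ± 27.4 to 206 ± 14.7 CPM (n = 3 per group). *MT1X* rose by a log2 fold change of 2.74 ± 0.29 and *MT1F* by 2.68 ± 0.24. The control libraries together held 3 counts of *MT1G* and 1 of *MT1M*, against 453 and 49 in the ABS libraries. These were ratios of 143 (95% exact binomial interval 48.5 to 695) and 46.3 (7.93 to 1870) after scaling. The list's median depends on the rank of these 2 genes but not on the size of their ratios, while the camera test uses their values. Over the alternatives that tested them, apart from the 1.2-fold test, the log2 fold change lay between 6.44 and 7.844 for *MT1G* and between 4.465 and 7.069 for *MT1M*. *MT1A*, the member that did not pass, had a log2 fold change of 0.98 and an adjusted p of 0.696. *SLC30A1* (ENSG00000170385, chromosome 1, 211571568 to 211578742) rose from 31.2 ± 18.8 to 220 ± 58.2 CPM, a log2 fold change of 2.81 ± 0.32 with an adjusted p of 0.00186. Control replicate 3 lay above the other control libraries for *MT1E*, *MT1X*, *MT2A* and *SLC30A1*, and without it the *SLC30A1* change was 10.8-fold instead of 7.02-fold. Within replicates 1 and 2 the log2 fold change was 3.73 for *MT1E*, 2.11 for *MT2A* and 3.63 for *SLC30A1*, and within the replicate 3 pair it was 2.68, 1.09 and 1.53. The call of *MT2A* ended without control replicate 2 (adjusted p = 0.0544), and that of *MT1M* without control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2, at adjusted p of 0.16 to 0.244. The robust fit put *SLC30A1* at an adjusted p of 0.182 and *MT2A* at 0.14.

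**Figure D2:**
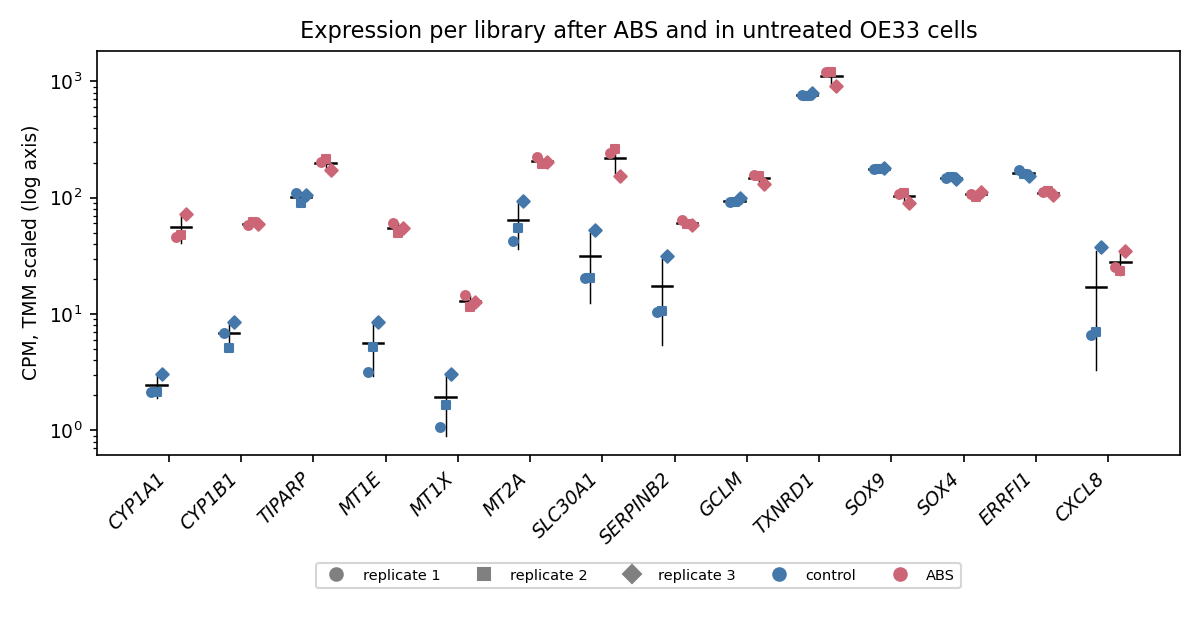
Expression of 14 genes in each library as TMM-scaled CPM on a log axis, with 1 point per library (blue control, red ABS, marker shape by replicate), a bar at the mean and a line of 1 SD to each side, n = 3 per group. The ABS points lie above all control points for *CYP1A1*, *CYP1B1*, *TIPARP*, *MT1E*, *MT1X*, *MT2A*, *SLC30A1*, *SERPINB2*, *GCLM* and *TXNRD1*, below them for *SOX9*, *SOX4* and *ERRFI1*, and overlap them for *CXCL8*.

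In the NRF2 antioxidant list, 3 of 24 members rose and 0 fell, and 7 were higher when adjusted over the list alone. *GCLM*, a subunit of the enzyme that limits glutathione synthesis, rose from 94.5 ± 4.25 to 147 ± 14.5 CPM, a log2 fold change of 0.64 ± 0.08 with an adjusted p of 0.00498. *TXNRD1*, a thioredoxin reductase, rose from 767 ± 24.8 to 1106 ± 168 CPM, and *OSGIN1*, a growth inhibitor induced by oxidative stress, from 11.4 ± 3.19 to 27.3 ± 2.43 CPM. *NFE2L2*, which encodes NRF2 itself, had a log2 fold change of 0.49 and an adjusted p of 0.0534, and *HMOX1*, heme oxygenase 1, one of 0.63 and 0.115. *NQO1* lay at 246 ± 13.1 CPM in control cells and 247 ± 3.58 CPM after ABS. The list's median was 0.07 and its camera adjusted p was 9.31e-06 (adjusted p = 0.113 with an estimated correlation). Leaving out control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2 ended the call of *TXNRD1* at adjusted p of 0.233 to 0.298. The call of *GCLM* ended without control replicate 1 (0.0586), control replicate 2 (0.0701) or ABS replicate 1 (0.0691), and that of *OSGIN1* without control replicate 2 (0.0579) or ABS replicate 1 (0.06). *NFE2L2* passed without control replicate 3 (0.000688) or ABS replicate 3 (0.0328), and with a term for the replicate 3 libraries *NFE2L2* (0.00112) and *HMOX1* (0.0328) passed. For *GCLM* and *TXNRD1* the log2 fold change was 0.76 and 0.68 within replicates 1 and 2 and 0.40 and 0.20 within the replicate 3 pair.

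Of 19 tested NF-kB inflammatory genes, 2 rose and 0 fell. These were *RELB*, an NF-kB subunit, with a log2 fold change of 0.66 ± 0.10, and *IRF1*, an interferon regulatory factor, with 0.71 ± 0.12. Adjusted over the list alone, 9 genes were higher and 1, *TNFAIP2* (−0.23), was lower. *PTGS2*, which encodes cyclooxygenase 2, had a log2 fold change of 1.18 (adjusted p 0.0551) and *BIRC3*, an inhibitor of apoptosis, one of 0.83 (0.0782). The list's median was 0.63, with a camera adjusted p of 4.05e-12 (adjusted p = 0.408 with an estimated correlation). *RELB* and *IRF1* lost their calls without control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2, at adjusted p of 0.06 to 0.222, and with library size alone, at 0.0509 and 0.0712. *PTGS2* passed without control replicate 3 (2e-04) or ABS replicate 3 (0.00892), and *BIRC3* without control replicate 3 (7.29e-06). Within the replicate 3 pair, with 1 library per group, the log2 difference was 0.19 for *PTGS2* and 0.29 for *BIRC3*. Within replicates 1 and 2 the log2 fold changes were 1.73 and 1.19, and this contrast was not tested. The log2 fold changes of *RELB* and *IRF1* were 0.72 and 0.91 within replicates 1 and 2 and 0.57 and 0.37 within the replicate 3 pair.

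Immediate-early and MAPK feedback genes had 2 of 23 members higher and 0 lower, both of the AP-1 family. *FOSL1* rose from 334 ± 44.3 to 470 ± 22.2 CPM, and *FOSB* from 3.16 ± 0.997 to 7.79 ± 1.73 CPM. Adjusted over the list alone, 8 genes were higher and 1, *PHLDA1* (−0.22), was lower, and *FOSL2* (0.51, adjusted p 0.0532) and *ATF3* (0.96, adjusted p 0.056) lay close to the threshold over all genes. The camera adjusted p was 5.45e-05 (adjusted p = 0.408 with an estimated correlation) at a median of 0.12. In the JAK-STAT3 list 1 of 15 genes rose and 0 fell. This gene was *SOCS1*, which encodes a feedback inhibitor of that pathway and went from 1.29 ± 0.199 to 3.82 ± 0.823 CPM. *BCL3* (0.53, adjusted p 0.0551), *MCL1* (0.40, 0.112), *IL6ST* (0.27, 0.266) and *IL6R* (0.48, 0.279) were also higher when adjusted over the list alone. The camera adjusted p of that list was 0.00135 (adjusted p = 0.422 with an estimated correlation), and its median was 0.12. *FOSL1*, *FOSB* and *SOCS1* lost their calls without control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2, at adjusted p of 0.159 to 0.277, and with library size alone, at 0.0675 to 0.0862. *FOSB* passed in 10 of the 20 alternatives, and *SOCS1* missed the threshold with limma-voom too (0.0576). The log2 fold changes of *FOSL1*, *FOSB* and *SOCS1* were 0.64, 1.71 and 1.76 within replicates 1 and 2 and 0.22, 0.54 and 1.14 within the replicate 3 pair. *FOSL2*, *ATF3* and *BCL3* passed without control replicate 3 (0.000466, 0.0016 and 0.00208) or ABS replicate 3 (0.0386, 0.0221 and 0.0476).

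All 16 tested interferon-stimulated genes had positive log2 fold changes over all libraries, with a median of 0.16. Within replicates 1 and 2, 13 were positive and 3 negative, and in the replicate 3 pair 15 were positive and 1 negative. Of the 16 genes, 0 passed the edgeR threshold over all genes, while 6 had an unadjusted p under 0.05, 6 were higher when adjusted over the list alone, 3 passed with DESeq2 and 0 with limma-voom. *OASL* (0.99, adjusted p 0.103), *IFIT3* (0.57, 0.0668), *IFIH1* (0.44, 0.138) and *DDX58* (0.42, 0.111), which encode antiviral effectors and RNA sensors, had the smallest adjusted p. The camera adjusted p was 2.04e-05 (adjusted p = 0.285 with an estimated correlation). Over all genes, *IFIT3* (0.0387), *OASL* (0.00239) and *DDX58* (0.0249) passed without control replicate 3, and *DDX58* (0.0438) without ABS replicate 3. With the term for the replicate 3 libraries *OASL* (0.00957), *IFIT3* (0.00969), *DDX58* (0.0229) and *IFIH1* (0.0299) passed. The replicate 3 pair differed by 0.41 for *OASL*, 0.69 for *IFIT3*, 0.39 for *IFIH1* and 0.17 for *DDX58*, and replicates 1 and 2 by 1.37, 0.50, 0.46 and 0.55. In the cell junction list 0 of 23 genes passed with edgeR, 6 were higher at an unadjusted p under 0.05, 2 passed with DESeq2 and 0 with limma-voom. Adjusted over the list alone, the tight junction genes *CLDN4* (0.54, adjusted p 0.103) and *OCLN* (0.45, 0.119) were higher. The camera adjusted p was 0.00246 (adjusted p = 0.633 with an estimated correlation), and the median was 0.08. *CLDN4* and *OCLN* passed without control replicate 3 (0.00369 and 0.00474) or ABS replicate 3 (0.00764 and 0.0271). In the replicate 3 pair the log2 differences of *CLDN4* and *OCLN* were −0.01 and 0.01, against 0.82 and 0.68 within replicates 1 and 2. This contrast was not tested. Of 17 YAP-TEAD targets 0 passed with edgeR, DESeq2 or limma-voom, 0 were called when adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05. *CTGF*, a matricellular protein gene, lay at 3.36, 3.96 and 13.8 CPM in the control libraries and at 15.1 ± 0.392 CPM (mean ± SD, n = 3) after ABS, and passed only without control replicate 3 among the libraries left out (9.03e-06), and also with the term for the replicate 3 libraries (0.0164). This list had a median of 0.12 and a camera adjusted p of 0.00593 (adjusted p = 0.772 with an estimated correlation), and its call ended without control replicate 1 (0.262), control replicate 2 (0.198) or ABS replicate 3 (0.108).

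**Figure D3:**
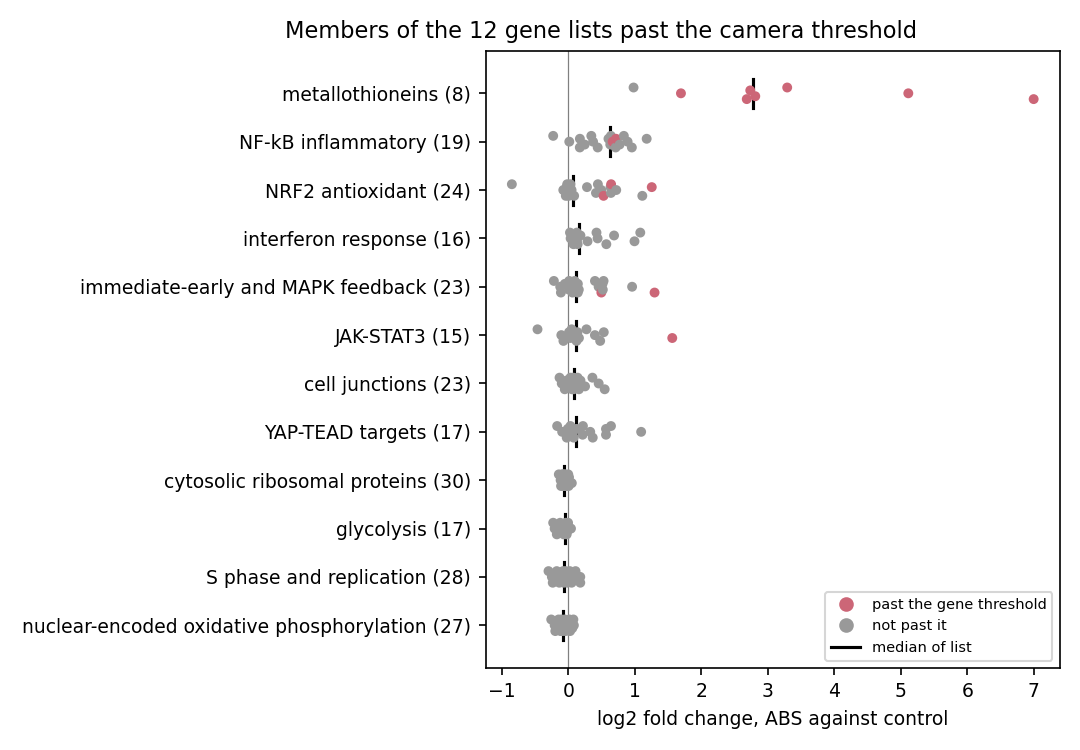
Log2 fold changes of the tested members of the 12 gene lists past the camera threshold, with 1 point per gene, red for genes past the edgeR threshold, and a black line at the median of each list; the number of tested members stands in brackets. The metallothionein list, which holds *SLC30A1*, has a median of 2.77 and the NF-kB list of 0.63, the other medians lie between −0.09 and 0.16, and the points of *MT1G* and *MT1M* rest on 3 and 1 control counts.

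*SOX9* (ENSG00000125398, chromosome 17, 72121020 to 72126420), a regulator of progenitor cells in columnar epithelium, fell from 178 ± 1.15 to 102 ± 10.9 CPM (n = 3 per group), a log2 fold change of −0.79 ± 0.08 with an adjusted p of 0.000933. *SOX4* and *SOX13* fell too, with log2 fold changes of −0.47 ± 0.07 and −0.45 ± 0.08. *ERRFI1* fell from 162 ± 9.35 to 110 ± 3.73 CPM. Further lower genes were *PLEKHH3* (−0.91), *MEX3A* (−0.70), which encodes an RNA-binding protein, *EPOP* (−0.54), which encodes a partner of Polycomb repressive complex 2, and *OGT* (−0.51), which encodes the O-GlcNAc transferase. Within replicates 1 and 2 the log2 fold change was −0.70 for *SOX9*, −0.52 for *SOX4* and −0.56 for *ERRFI1*, and within the replicate 3 pair −0.99, −0.37 and −0.53. *SOX9* passed in all 20 alternatives. Other calls ended when single libraries were left out, that of *ERRFI1* without control replicate 1 (0.0586), control replicate 2 (0.0561) or ABS replicate 1 (0.0691). Those of *SOX4*, *SOX13*, *PLEKHH3*, *MEX3A*, *EPOP* and *OGT* ended without control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2, at adjusted p of 0.11 to 0.277. With library size alone *SOX13*, *MEX3A*, *EPOP* and *OGT* lay at 0.0578 to 0.0737.

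Among the lists, 4 were called lower by camera, each by a small shift of many genes. Of 30 ribosomal protein genes 27 had negative log2 fold changes, with a median of −0.06 and an adjusted p of 0.0239 (adjusted p = 0.834 with an estimated correlation). Of 17 glycolytic enzyme genes, among them the hexokinase gene *HK2* (−0.21), 16 were negative, with a median of −0.05 and an adjusted p of 0.0239 (adjusted p = 0.772 with an estimated correlation). Of 28 S phase and replication genes 20 were negative, among them *E2F1* (−0.22) and the replication licensing factor gene *CDT1* (−0.25), with a median of −0.07 and an adjusted p of 0.0286 (adjusted p = 0.408 with an estimated correlation). Of 27 nuclear-encoded oxidative phosphorylation genes 20 were negative, with a median of −0.09 and an adjusted p of 0.0355 (adjusted p = 0.687 with an estimated correlation). In these lists 0 genes passed with edgeR, over all genes or adjusted over the list alone, and 0 with DESeq2 or limma-voom, while 0, 3, 5 and 1 were lower at an unadjusted p under 0.05. The calls of the ribosomal list ended without control replicate 1 (0.262), control replicate 2 (0.789) or ABS replicate 3 (0.299), and those of the glycolytic list without control replicate 1 (0.262), control replicate 2 (0.267) or ABS replicate 3 (0.519). The S phase list missed the threshold without control replicate 1 (0.092), control replicate 3 (0.0634) or ABS replicate 3 (0.126). The oxidative phosphorylation list missed it without control replicate 1 (0.186), control replicate 2 (0.267), ABS replicate 2 (0.105) or ABS replicate 3 (0.108).

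In total 12 of 43 lists were called by camera, 8 higher and 4 lower. With an estimated correlation 0 were called and 4 had an unadjusted p under 0.05, and fry called 3, metallothioneins (0.0103), NRF2 antioxidant genes (0.0103) and S phase genes (0.0382). The estimated correlation was −0.0178 for NRF2 and −0.00956 for S phase genes, below the preset 0.01. A higher correlation between genes was therefore not what weakened these lists, and the reason was not tested. In the other called lists it lay between 0.057 and 0.746. With the preset correlation the count of called lists was 7 without control replicate 1 and 7 without ABS replicate 3. The 7 lists called in every fit that left out a library were metallothioneins, NF-kB, NRF2, interferon, immediate-early, JAK-STAT3 and cell junctions. Within replicates 1 and 2, 14 lists were called. These were the 12 without S phase genes (0.111) and with integrated stress (0.0345, lower), the DNA damage response (0.0319, higher) and mitochondrially encoded mRNAs (8.58e-09, lower). With a term for the replicate 3 libraries 14 were called, the 12 with heat shock (0.0238, higher) and mitochondrially encoded mRNAs (0.00965, lower). When that term was used with an estimated correlation 0 were called, and 3 had an unadjusted p under 0.05. In the replicate 3 pair the list medians were 2.23 for metallothioneins, 0.21 for interferon, 0.14 for NF-kB, 0.12 for NRF2, 0.04 for JAK-STAT3, 0.01 for cell junctions, −0.03 for glycolysis and −0.10 for S phase, against 3.45, 0.19, 0.91, 0.05, 0.17, 0.12, −0.06 and −0.04 within replicates 1 and 2. For 4 called lists the median in the replicate 3 pair had the other sign. YAP-TEAD targets had a median of −0.13 there, with 13 of 17 genes negative, and 0.30 within replicates 1 and 2. Immediate-early genes had 12 of 23 negative there, ribosomal protein genes 19 of 30 positive and oxidative phosphorylation genes 17 of 27 positive.

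Several genes of interest for reflux did not pass. *CXCL8*, the interleukin 8 gene, lay at 6.55, 7.01 and 37.4 CPM in the control libraries and at 25.4, 23.4 and 34.9 CPM after ABS, a log2 fold change of 0.71 ± 0.50 with an adjusted p of 0.712. Without control replicate 3 its log2 fold change was 2.04, with an adjusted p of 1.5e-05, and with the term for the replicate 3 libraries 1.08, with an adjusted p of 0.0335. Within the replicate 3 pair its log2 difference was −0.10. *CDX2*, an intestinal transcription factor gene, had a log2 fold change of 0.45 (adjusted p 0.414), and *VDR*, the vitamin D receptor gene, one of 0.27 (0.263). *CDKN1A*, a cell cycle inhibitor gene, had 0.28 (0.457) and passed without control replicate 3 (0.00833). *DDIT3* (−0.30, 0.763) and *HSPA1A* (0.10, 0.933), markers of endoplasmic reticulum and heat stress, and *MYC* (0.06, 0.855) and *ERBB2* (−0.03, 0.93) did not pass either. *NR1H4*, the farnesoid X receptor gene, had 0 counts in all libraries. Taken singly, each library excluded only levels above a limit of 0.119 to 0.135 CPM, depending on the library. All libraries together would set a lower limit on its mean level, which was not computed. *TP63* (8 counts over the control and 0 over the ABS libraries), *NR0B2*, a target of that receptor (5 and 1), *IL6* (11 and 5) and the bile acid receptor gene *GPBAR1* (4 and 7) were too low to test.

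Other lists of stress and damage responses than those described above were not called. Camera adjusted p-values were 0.193 for heat shock, 0.378 for the unfolded protein response, 0.29 for the integrated stress response, 0.159 for hypoxia, 0.159 for autophagy, 0.797 for the vacuolar ATPase and lysosome, 0.309 for antioxidant peroxidases, 0.243 for the DNA damage response, 0.0756 for apoptosis, 0.29 for base excision repair, 0.834 for double-strand break repair and 0.159 for G2/M phase. Adjusted over the list alone, *HSPA8* (0.38), *SEC24D* (0.34), *BMF* (1.27), *KIF23* (0.34), *GADD45A* (0.48), *PLK2* (0.51), *SLC7A11* (0.64), *PPP1R15A* (0.69) and *ADM* (0.46) were higher in their lists. The integrated stress genes *CEBPB* (−0.50) and *DDIT4* (−0.80) and the hypoxia genes *PFKFB3* (−0.34), *BHLHE40* (−0.40), *PFKFB4* (−0.72), *EGLN3* (−0.54) and *VEGFA* (−0.46) were lower. The heat shock list as a whole was called higher by camera without control replicate 3 (0.0022), ABS replicate 1 (0.0212) or ABS replicate 2 (0.0441). Apoptosis was called higher without control replicate 2 (0.0276). The integrated stress list was called lower without control replicate 3 (0.00011) or ABS replicate 2 (0.046). So was the hypoxia list, without control replicate 3 (0.00822) or ABS replicate 2 (0.0049). For both repair lists the median and the mean differed in sign (0.02 and −0.04, 0.03 and −0.01).

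Signalling, differentiation and metabolic lists not called were EGFR and ERBB signalling (adjusted p 0.255), Wnt and Notch targets (0.257), TGF-beta targets (0.937), epithelial-mesenchymal transition (0.255), intestinal and columnar differentiation (0.937), squamous differentiation (0.667), antigen presentation (0.333), chromatin modifiers (0.582), nuclear receptors and clock genes (0.792), ribosome biogenesis (0.577), bile acid sensing and transport (0.378), acid sensing (0.577), cholesterol efflux (0.255), cholesterol synthesis (0.415) and fatty acid synthesis (0.884). In the EGFR list, 1 of 13 genes rose and 1 fell over all genes, the ligand gene *TGFA* (0.62 ± 0.09, from 196 ± 16.2 to 301 ± 35.8 CPM) and the inhibitor gene *ERRFI1*. Adjusted over the list alone, the ligand genes *EPGN* (2.48) and *EREG* (0.42) were also higher and *GRB7* (−0.54) was also lower. The call of *TGFA* ended without control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2, at adjusted p of 0.105 to 0.159. In the intestinal list *SOX9* fell, and fry and camera differed in sign. Of the TGF-beta targets, *INHBA* (0.99) and *KLF4* (0.31) were higher and *ID1* (−0.41) and *SMAD6* (−0.52) lower when adjusted over the list alone, and in this list and the clock list the median (−0.04 in each) and the mean (0.01 in each) differed in sign. *NR1D2* (0.47), *HDAC9* (0.57) and *RRP12* (0.30) were higher when adjusted over the list alone. Of the 129 genes named by the rule or in the text that did not pass over all genes, 57 passed without control replicate 3 and 25 without ABS replicate 3, and 0 without any other single library. With the term for the replicate 3 libraries 60 of them passed, and within replicates 1 and 2, 91. The cholesterol synthesis list was called lower by camera without control replicate 3 (9.81e-06), ABS replicate 1 (0.0174) or ABS replicate 2 (0.0228). Fatty acid synthesis was called lower without control replicate 3 (0.0434).

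The control lists were not called, with adjusted p of 0.0516 for replication-dependent histones, 0.122 for mitochondrially encoded mRNAs, 0.707 for housekeeping genes and 0.617 for immune cell markers. Adjusted over the list alone, the immune marker gene *ITGAM* (from 0.302 ± 0.153 to 0.923 ± 0.254 CPM) was higher. The histone list was called higher without control replicate 3 (0.0313) or ABS replicate 1 (0.0212), with library size alone (0.0389) and with log2 CPM and a trend (0.0463). The mitochondrial list was called lower without control replicate 3 (1.28e-07) or ABS replicate 2 (0.0049). Its direction turned between the libraries, with 13 of 13 genes negative within replicates 1 and 2 (median −0.17) and 12 of 13 positive in the replicate 3 pair (median 0.11). Summed over their genes, fibroblast markers lay between 3.10 and 5.12 CPM per library, immune cell markers between 7.99 and 10.8 CPM and endothelial markers at up to 14.4 CPM, with the 2 groups overlapping. Squamous genes lay between 224 and 278 CPM, also with overlap.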

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

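The alternatives that left out both replicate 3 libraries, fitted a term for them or removed GC and length trends were chosen after seeing the data. The 60 genes kept their direction in all 20 alternatives of the gene test that tested them, and no list call turned. For the fits that left out libraries the direction of these genes was nearly fixed, since the groups did not overlap in any of the 60. Counts stayed within 1.5 times under size factors by relative log expression (62), upper quartile factors (57), the filter on CPM (59), limma-voom (62), the robust fit (70), protein-coding genes alone (57) and removal of GC and length trends (70). Library size alone gave 35 genes, 31 higher and 4 lower, all among the 60. Without a filter 409 passed, 291 higher and 118 lower, 41 with an absolute log2 fold change of at least 1, and DESeq2 gave 233, 165 higher and 68 lower, 29 of them at that size. The share of higher genes was 85.0%, and 71.1% and 70.8% in these fits. Against a 1.2-fold change 14 passed. The labels pair no libraries. Deviations from the group mean correlated at 0.0425, 0.0333 and 0.167 between libraries of the same number. Between libraries of different numbers the correlation was 0.0934 for control 1 and ABS 2, 0.0311 for control 2 and ABS 1, and −0.125 to −0.0581 for pairs with a replicate 3 library. The replicate block gave 350 genes, 244 higher, 106 lower and 39 at an absolute log2 fold change of at least 1. Without both replicate 3 libraries 1813 passed, 1079 higher, 734 lower and 133 at that size. With the term for them 465 passed, 308 higher, 157 lower and 41 at that size. Fits that left out a library gave 12 to 438 genes, 11 to 321 higher, 1 to 117 lower and 8 to 66 at that size. Leaving out control replicate 3 or ABS replicate 3, which stood apart from their groups, lowers the spread by construction, and leaving out any library leaves fewer. The cause of the other shifts was not tested. For the lists, 12 were called, 0 with an estimated correlation, 3 with fry, 7 to 18 when a library was left out, and 0 with the term for the replicate 3 libraries and an estimated correlation together. The other list alternatives gave between 12 and 14. Over the genes named by the rule or in the text and their alternatives other than the 1.2-fold test, 2964 results kept their side of the threshold, 222 lost it, 392 gained it and 0 reversed. At this depth 1.5-fold changes were recovered in 45.3% of simulated cases, so the count of 60 sets no upper limit on the genes that differed.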

Other observations

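The tests of *SLC30A1* against shared reads, of the mitochondrial share, of the SOX family and of transcription factors, and all comparisons within replicates 1 and 2 or the replicate 3 pair, were chosen only after the result concerned had been seen.

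Further genes past the threshold fell outside the lists. *SLC16A6*, a member of the monocarboxylate transporter family, rose from 2.58 ± 0.407 to 11.9 ± 3.82 CPM (mean ± SD, n = 3 per group), a log2 fold change of 2.20 ± 0.25 with an edgeR adjusted p of 0.00195. *SERPINB2*, which encodes plasminogen activator inhibitor 2, rose from 17.6 ± 12.2 to 60.8 ± 2.88 CPM, and by 5.77-fold instead of 3.45-fold without control replicate 3. *PRDM1*, which encodes a transcriptional repressor, rose from 2.85 ± 0.760 to 7.35 ± 0.930 CPM. The adaptor gene *DAPP1* (0.88 ± 0.11), the long non-coding RNA *LINC00511* (0.80 ± 0.09), *CEBPD* (0.79 ± 0.11), *JARID2* (0.68 ± 0.09), a partner of Polycomb repressive complex 2, and the Wnt ligand gene *WNT7B* (0.50 ± 0.09) were also higher, and were named after their values were seen. So were *APOL6* (0.60 ± 0.10), *DTX3L* (0.53 ± 0.08) and *IFIT5* (0.47 ± 0.09), which interferon is known to induce. *SLC16A6*, *DAPP1* and *LINC00511* kept their calls with every library left out. The calls of *SERPINB2*, *WNT7B*, *APOL6*, *DTX3L* and *IFIT5* ended without control replicate 1, control replicate 2, ABS replicate 1 or ABS replicate 2, at adjusted p of 0.0996 to 0.295, and with library size alone those of *SERPINB2* (0.0819), *WNT7B* (0.0925) and *IFIT5* (0.0857). The robust fit put *SERPINB2* at 0.318. That of *CEBPD* ended without the same libraries, at 0.0523 to 0.112, that of *PRDM1* without control replicate 2 (0.144), ABS replicate 1 (0.198) or ABS replicate 2 (0.122), and that of *JARID2* without control replicate 1 (0.0713), control replicate 2 (0.0989) or ABS replicate 1 (0.0543).

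*CYP1A1*, *CYP1B1* and *TIPARP* are textbook targets of the aryl hydrocarbon receptor, and a candidate explanation is that this receptor was active in ABS cells. Their rise did not come from a single library, since the 3 genes kept all 18 calls in the 6 fits that left out a library. Of 11 further targets chosen before their values were seen, 9 were tested, with a median log2 fold change of 0.276 (bootstrap SD 0.117). The bootstrap drew genes and not libraries, so its SD gives the spread among targets and not between replicates. Of the 9 targets, 8 were positive, among them *AHRR* (1.19, adjusted p 0.106), *EREG* (0.42, 0.103) and *ABCG2* (0.36, 0.22). The positive targets also included *ALDH3A1* (0.065, 0.915) and *NQO1* (0.003, 0.996), which hardly moved, and *CYP2S1* (−0.201, 0.678) was negative. As a group the 9 targets lay above the other genes (camera p 0.00211, and 0.033 with an estimated correlation), while 0 passed with edgeR or limma-voom, 2 with DESeq2 and 3 at an unadjusted p under 0.05. Their median was 0.43 within replicates 1 and 2 and 0.07 in the replicate 3 pair, with 7 of the 9 positive in each. Whether bile salts, acid or the exposure medium was responsible stays open, since 0 groups were labelled as given the medium without bile salts or acid, and these cannot be told apart in this design. Whether the untreated cells had a change of medium was not stated.

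The joint rise of metallothionein genes and *SLC30A1* may be a response to zinc or another metal. Reads shared between near-identical metallothionein genes could not account for *SLC30A1*, which has no such copy and had a log2 fold change of 2.81 ± 0.32. For the single metallothionein genes this stays open, since the share of 50-base windows found in no other gene was as low as 81.7% in *MT1X* and the counting of reads with several positions was not stated. *SLC39A10*, which zinc is known to repress, had a log2 fold change of −0.0927 ± 0.196, a spread too wide to tell a fall from no change. With the term for the replicate 3 libraries, added after seeing the data, it was −0.079 ± 0.0642. That narrower spread still did not tell a small fall from no change. Zinc itself therefore cannot be told apart from other inducers of these genes.

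For the separation of both replicate 3 libraries, a trend with gene length or GC content in the second principal component was argued against by rank correlations across genes, which are not independent replicates, of −0.0895 and −0.0957. After removal of both trends the second component, with 25.8% of the variance, still held the replicate 3 libraries outside the range of the others. More mitochondrial RNA was argued against too, since 0 of the replicate 3 libraries exceeded the highest share among the others. A difference in culture or library batch stays open, since the labels give neither, and no biological explanation was tested.

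A further hypothesis was that the fall of *SOX9*, *SOX4* and *SOX13* may extend to the family. The other 7 tested SOX genes were all negative, with a median log2 fold change of −0.661 (camera p 2.11e-06, and 0.0408 with an estimated correlation), of −0.56 after removal of GC and length trends, and between −1.02 and −0.541 over the alternatives. The fall of these 7 genes as a group was absent in the replicate 3 pair, where 4 were positive and the median was 0.00, against −1.02 and 7 negative within replicates 1 and 2. The hypothesis therefore rests on replicates 1 and 2. Of the 7, *SOX12* (−1.03, adjusted p 0.0668) and *SOX21* (−0.72, 0.115) came nearest the threshold, which 0 passed with edgeR or limma-voom, 2 with DESeq2, 2 with the term for the replicate 3 libraries and 5 at an unadjusted p under 0.05. The genes past the threshold may also be rich in transcription factors, which made up 12 of 60, or 20% against 6.87% of all 13768 tested genes, an odds ratio of 3.42 (95% interval 1.65 to 6.56, two-sided Fisher exact p 0.000669). Of these 12, 9 were higher and 3 lower. This share rests on calls that 1 library can remove, since 1 of the 12, *SOX9*, passed in all 6 fits that left out a library. Transcription factors were 2 of 17, 1 of 12, 1 of 13 and 2 of 18 calls without control replicate 1, control replicate 2, ABS replicate 1 and ABS replicate 2, with odds ratios of 1.13 to 1.81 and Fisher p of 0.328 to 0.604. The 95% intervals of these 4 fits reached from as low as 0.0264 to as high as 8.5, so so few calls cannot tell 3.42 from 1. The odds ratios were 3.29 (2.53 to 4.24) without control replicate 3 and 2.68 (1.88 to 3.75) without ABS replicate 3, and 2.27 with library size alone (95% interval 0.685 to 5.92). They were 3.52 (2.49 to 4.9) with DESeq2 and 3.63 (1.8 to 6.83) with limma-voom.

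The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with a result as large is never under 0.1. With edgeR, 1 of the 10, the real one, gave as many as 60 genes, and the highest count in the others was 0. For the lists, 4 of the 10 gave as many as the real 12, and the highest of the others was 20, which set control replicates 1 and 2 with ABS replicate 2 against the rest. A split with ABS replicate 1 in that place gave 19. Apart from the real split, the 4 splits with both replicate 3 libraries on the same side gave 20, 19, 12 and 9 lists, and the 5 that set them on different sides gave 0 to 10. With a term for the replicate 3 libraries 14 lists were called in the real split, and 0 with an estimated correlation as well.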
